A study of Sus scrofa with 24 samples.

How the data were processed

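Expression was measured in 24 pieces of porcine aortic valve leaflet, 6 in each of 4 groups: static or cyclically stretched for 24 h at 37 C, without agents or with 5HT plus Fluox. Per the labels, 6 ug of total RNA per piece was labelled for 1 Affymetrix porcine array, and no RNA was pooled. The deposited values of the authors are GCRMA probe set summaries in log2 units, made with Partek and GCRMA per the labels, and their versions were not given. The values were checked to be on the log2 scale and were used as deposited. A table of the authors' analysis of variance was deposited beside them, with p-values (unadjusted, and adjusted by Benjamini-Hochberg) and signed linear fold changes in other units for 4 pairwise comparisons. It was compared with the fits below and used for nothing else. Whether the authors' model held a batch or scan term was not stated, and no scan dates were at hand.

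Of 24123 probe sets 124 controls were left out and 23999 tested. Symbols came from the platform annotation: 10069 probe sets carried 1 symbol, 198 carried several and 13732 carried none, so that many called probe sets could not be named. The 10069 covered 6765 symbols, of which 2261 had several probe sets. Arrays give no counts, so their number, 6 per group, limits the precision.

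The tests, gene lists, naming rule and most of the alternatives below were fixed before the data were examined. 1 linear model of the 4 group means was fitted to all arrays with limma (version 3.58.1, R 4.3.3), followed by eBayes with default settings. It gave 5 contrasts: stretch against static without and with agents, agents against no agents in static and in stretched tissue, and the interaction. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the 23999 probe sets of a contrast, and a probe set was called at an adjusted p under 0.05. Values after a gene's symbol are log2 changes with their standard error (SE). Because arrays of different groups may share an animal, the p-values measure the spread between samples.

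For the 30 gene lists camera of limma was used with a preset correlation of 0.01, 1 probe set per symbol (that of the highest mean) and at least 5 measured members, adjusted over the lists. Members were counted as called over all probe sets and as adjusted over the list alone. None of the list calls in any contrast held with an estimated correlation, and that adjusted p is given beside each. Lists for the tissue and its matrix covered serotonin genes (receptors, transport and metabolism), fibrillar collagens, elastic fibre with proteoglycan and matricellular genes, matrix-degrading enzymes, contractile and myofibroblast genes, and osteogenic and chondrogenic genes. Signalling lists covered TGF-beta, YAP/TAZ and SRF targets, inflammatory genes, interferon-responsive genes, immediate-early genes, Wnt with Notch and BMP pathways, adrenergic with cyclic AMP and neuronal signalling, and the circadian clock. Lists of metabolism and stress covered the cell cycle, glycolysis and hypoxia, oxidative phosphorylation, sterol synthesis and uptake, lysosome and phospholipid storage, the unfolded protein and amino acid response, heat shock, oxidative stress, p53 response and apoptosis, and ribosomal proteins. Marker lists covered valve endothelial cells, macrophages and leukocytes, cardiac muscle, vascular smooth muscle and pericytes, erythrocytes and platelets, and valve interstitial fibroblasts.

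Named genes were the 12 largest rises and 12 largest falls of each pairwise comparison (6 and 6 for the interaction) among called probe sets with 1 symbol and a mean log2 value of at least 5 in the higher group. Where none was called, the 4 of smallest unadjusted p were named. Up to 4 members of smallest p per list were added, and HTR2A, HTR2B, SLC6A4, ACTA2 and COL1A1 in every comparison.

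Alternatives set at the same time were the replicate number as a block, limma with trend and robust variances, no moderation, leaving out dim probe sets (mean log2 under 4), quantile normalization, centring each array on its brighter probe sets, fitting only the 2 groups compared, array weights, camera with an estimated correlation, averaged probe sets per symbol, and leaving out each array in turn. Chosen after seeing the data were the 3′ to 5′ difference of GAPDH and EF1A control probe sets as a covariate, and leaving out the 3 arrays in which it exceeded 2.5. Array measures were compared by exact two-sided permutation tests, adjusted over 40 tests.

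The fit was tested on simulated data. These were normal noise with each probe set's own mean and residual spread, in which 50 probe sets per size were shifted in the stretched group without agents. It recovered 30%, 50%, 86% and 100% of shifts of 0.5, 1, 2 and 4 log2, with 5 other calls, and camera called the 1 shifted list and 0 others. The simulated noise was independent between genes. It therefore cannot show how often camera calls lists falsely where genes are correlated, as in the real data. Tables were handled with pandas 2.3.3 and drawn with matplotlib 3.10.9.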

Results

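Gene expression was measured in pieces of porcine aortic valve leaflet that had been kept in culture medium for 24 h. The pigs were between 12 and 24 months old, and a piece of 15 by 10 mm was taken from the middle of each cusp. The 24 pieces fell into 4 groups of 6. Static pieces lay in medium, and stretched pieces were sutured at their ends and pulled cyclically in a tensile bioreactor. Under each condition 1 group received no agents and the other received 5HT (serotonin) plus Fluox, at doses not given in the sources used here. Each RNA was read on its own Affymetrix porcine array as log2 values, and 23999 probe sets other than controls were tested, of which 10069 carried exactly 1 gene symbol (6765 different symbols). The labels call the arrays biological replicates. Leaflets of each valve were randomised over the groups, so arrays of different groups may come from the same animal, and which ones do was not given. The number of arrays, 6 per group, limits the precision of every value below.

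Arrays of stretched tissue differed from static arrays in their control probe sets for RNA quality. The array reads the 3′ and the 5′ end of GAPDH and EF1A transcripts, and the difference between both ends widens when RNA is degraded or incompletely copied. Averaged over both genes, this 3′ to 5′ difference was 0.77 ± 0.14 log2 (SD, n = 6) in static and 2.09 ± 0.71 in stretched tissue without agents (exact permutation test, p = 0.00216, the smallest that 6 against 6 arrays can give; adjusted p = 0.00618 over 40 such tests). With 5HT plus Fluox it was 0.82 ± 0.11 in static and 2.64 ± 1.07 in stretched tissue (exact permutation test, p = 0.00216, adjusted p = 0.00618). Between tissue with and without the agents it differed by 0.05 log2 in static tissue (exact permutation test, p = 0.515) and by 0.55 in stretched tissue (exact permutation test, p = 0.355). Probe sets for 18S and 28S ribosomal RNA read 1.90 and 2.07 log2 higher in stretched than in static tissue without agents. Because this measure moved together with stretch, the median of each gene list below is also given from a fit with the 3′ to 5′ difference as a covariate.

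**Figure D1:**
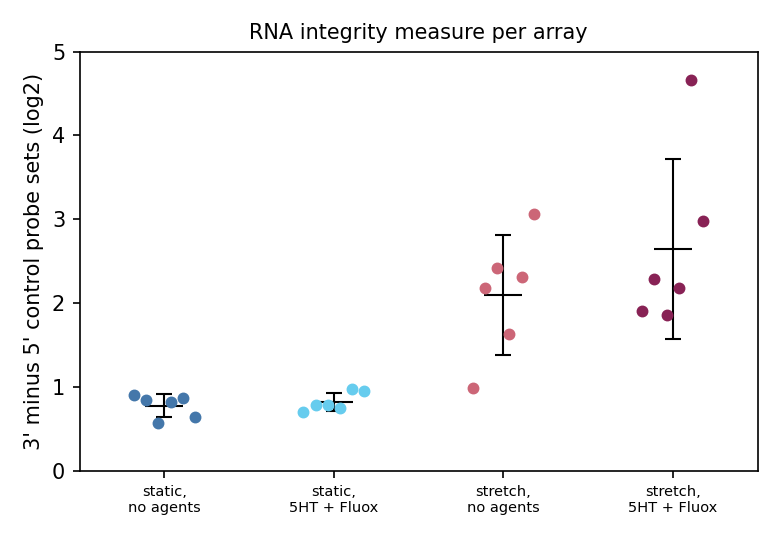
The 3′ minus 5′ difference of the GAPDH and EF1A control probe sets (log2, vertical axis) is plotted for each of the 24 arrays by group; points are arrays, and the horizontal mark and bars give the group mean and SD (n = 6). Static arrays lie between 0.57 and 0.97, and stretched arrays between 0.98 and 4.66.

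The first comparison asks how cyclic stretch changes the expression of valve tissue without agents. The list test called glycolysis and hypoxia genes (21 of 23 members lower) and endothelial markers (12 of 18 lower) downward. It called elastic fibre and proteoglycan genes (14 of 19 higher), interstitial fibroblast markers (13 of 18) and contractile genes (10 of 20) upward. None of these 5 list calls held with an estimated correlation (adjusted p = 0.0543, 0.343, 0.204, 0.321 and 0.262 in that order). The lactate transporter SLC16A3 fell from a mean of 8.79 to 2.59, at the bottom of the scale, so that its fall was at least that large (log2 change -6.20, SE 0.10, adjusted p = 1.6e-21), and the glucose transporter SLC2A1 had a log2 change of -4.64 (SE 0.42, adjusted p = 7.0e-08). The matrix protein gene CILP changed by 4.87 (SE 0.66, adjusted p = 1.0e-05), and THY1, a surface marker of fibroblasts, by 3.76 (SE 0.27, adjusted p = 5.0e-09). Of the 23999 probe sets, limma called 12600 (52.5%), 7067 higher and 5533 lower in stretched tissue; 3213 were at least 2-fold higher and 3659 at least 2-fold lower. With the 3′ to 5′ difference as a covariate the count was 5176, of which 4548 were among the 12600 and in the same direction. Which direction held more calls depended on the scaling and the filter. Centring each array on its brighter probe sets, which moved the median change of all probe sets by up to 0.22 log2, gave 11474 higher and 4482 lower calls. Lower calls were more frequent after quantile normalization (4720 higher, 5093 lower), with dim probe sets left out (3362 and 4759), when only these 2 groups were fitted (4208 and 4251) and with the covariate (2123 and 3053).

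The other large rises among named genes were in C1QTNF3, a secreted protein of the C1q and tumour necrosis factor family (5.18, SE 0.33, adjusted p = 1.0e-09), and in DES, the muscle intermediate filament desmin (4.74, SE 0.90, adjusted p = 0.000350). They were followed by FAM84A, ISLR, the stress-inducible GADD45G, FAM46C, FXYD7, S100A1, the water and glycerol channel AQP3, the heat shock gene HSPA6 and the growth factor gene HBEGF, with changes from 4.62 down to 4.02 and adjusted p from 4.2e-09 to 0.00133. Of these 12 rises, 9 had all 6 stretched arrays above every static array; for CILP, DES and HBEGF it was 5 of 6. ECSCR, an endothelial surface protein, was among the falls (-6.47, SE 0.38, adjusted p = 3.5e-10). CDA, an enzyme of pyrimidine salvage, changed by -5.76 (SE 0.50, adjusted p = 4.1e-08) and ACVR1B, a receptor for activin, by -5.03 (SE 0.43, adjusted p = 3.7e-08). MPI, CLK2, IL27RA, the fatty acid desaturase SCD, ARAP3, CHI3L1 and the interferon-inducible GBP1 followed with changes from -4.72 to -4.11. All 12 falls had 6 of 6 stretched arrays below every static array. Stretched means of SLC16A3, MPI (2.73), CDA (2.98), ECSCR (3.25) and ARAP3 (3.36), and static means of DES (2.68), S100A1 (3.22), FAM84A (3.22), ISLR (3.27) and HBEGF (3.30), lay near the bottom of the scale. The changes of these genes may be compressed and have no order of size. GBP1 lost its call with the covariate (-2.09, adjusted p = 0.186). Another probe set of CILP did not pass the test (0.19, adjusted p = 0.334). Another of DES read -0.46 (adjusted p = 0.341).

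Most glycolysis and hypoxia genes fell. Of 23 measured members 21 were lower and 1 higher, the same numbers as adjusted over the list alone, with a median log2 change of -2.00 (4.00-fold lower; camera, adjusted p = 5.4e-12, adjusted p = 0.0543 with an estimated correlation). Besides SLC16A3 and SLC2A1, hexokinase HK1 (-2.85, SE 0.17), enolase ENO2 (-3.33, SE 0.24) and glucose phosphate isomerase GPI (-2.93, SE 0.25) were lower in 6 of 6 arrays. With the 3′ to 5′ difference as a covariate the median was -1.64 with 20 members lower. In the list of sterol synthesis and uptake genes 9 of 18 were lower and 0 higher, also adjusted over the list alone (median -1.12, adjusted p = 0.00901, adjusted p = 0.449 with an estimated correlation). Squalene synthase FDFT1 (-1.87, SE 0.27) was among them, as were SCD and FADS1 (-2.90, SE 0.42), fatty acid desaturases that the list also holds. That list had a median of -0.51 and an adjusted p of 0.0748 with the covariate.

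In the list of elastic fibre, proteoglycan and matricellular genes 14 of 19 were higher and 0 lower, also adjusted over the list alone (median 1.62, 3.08-fold; adjusted p = 3.0e-06, adjusted p = 0.204 with an estimated correlation, median 1.57 with the covariate). ASPN (3.84, SE 0.46), FBLN1 (3.11, SE 0.38), LUM (2.17, SE 0.27) and SPARC (2.09, SE 0.27), all secreted components of connective tissue, were higher in 6 of 6 arrays. Of 18 markers of valve interstitial fibroblasts 13 were higher and 2 lower, also adjusted over the list alone (median 1.62, adjusted p = 7.6e-05, adjusted p = 0.321 with an estimated correlation, median 1.57 with the covariate). THY1 and the intermediate filament gene VIM (1.69, SE 0.22) were among them. Fibrillar collagen and collagen processing genes went both ways, 9 of 16 higher and 6 lower, also adjusted over the list alone (median 0.87, mean -0.03, adjusted p = 0.418, median 0.58 with the covariate). COL3A1 fell (-3.04, SE 0.40, adjusted p = 6.6e-06) and COL5A2 rose (2.07, SE 0.36, adjusted p = 0.000144), and COL1A1, which was to be reported in any case, had no probe set under that symbol here. Of 15 osteogenic and chondrogenic genes 7 were higher and 0 lower, also adjusted over the list alone (median 0.10, adjusted p = 0.000808, adjusted p = 0.129 with an estimated correlation, median 0.18 with the covariate). BMP4, a bone morphogenetic protein (2.28, SE 0.27), and MGP, an inhibitor of calcification (3.02, SE 0.39), were among them.

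Of 20 contractile and myofibroblast genes 10 were higher and 1 lower, also adjusted over the list alone (median 0.70, 1.62-fold; adjusted p = 4.8e-05, adjusted p = 0.262 with an estimated correlation, median 0.91 with the covariate). Calponin CNN1 changed by 3.17 (SE 0.50, adjusted p = 5.8e-05) and TAGLN by 2.02 (SE 0.34, adjusted p = 9.1e-05). ACTA2, the smooth muscle actin used to mark myofibroblasts, was 8.92 ± 1.23 in stretched and 6.66 ± 1.88 in static tissue (SD, n = 6; change 2.26, SE 0.68, limma adjusted p = 0.0105). Only 2 of 6 stretched arrays lay above every static array for ACTA2, and its call was lost with the covariate (1.90, adjusted p = 0.129) and when only these 2 groups were fitted (adjusted p = 0.0609). YAP/TAZ and SRF target genes had 7 of 14 higher and 2 lower, or 8 and 3 adjusted over the list alone (median 0.42, adjusted p = 0.0203, adjusted p = 0.204 with an estimated correlation, median 0.32 with the covariate). CYR61 (2.28, SE 0.29) and CRIM1 (2.14, SE 0.19) were higher. Averaging the probe sets of each gene ended that call (adjusted p = 0.166). Immediate-early genes had 9 of 17 higher and 2 lower, also adjusted over the list alone (median 0.50, adjusted p = 0.00208, adjusted p = 0.337 with an estimated correlation, median 1.22 with the covariate). JUN (2.22, SE 0.24) and KLF4 (1.58, SE 0.22) were higher.

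Markers of other cell types moved as well. Of 18 valve endothelial markers 12 were lower and 2 higher, also adjusted over the list alone (median -1.08, 2.12-fold lower; adjusted p = 0.0203, adjusted p = 0.343 with an estimated correlation, median -0.92 with the covariate). ECSCR, the junction protein CDH5 (-3.90, SE 0.35), the co-receptor ENG (-3.06, SE 0.23) and the angiopoietin receptor TEK (-3.52, SE 0.44) fell. AQP1 (2.35, SE 0.39) and LYVE1 (2.18, SE 0.38) were higher; both were chosen after their values were seen. The list was not called without stretched array 1 (adjusted p = 0.0897), nor with dim probe sets left out (adjusted p = 0.0572). Other probe sets of TEK (0.048 and 0.17) and CDH5 (-0.16, adjusted p = 0.156) did not pass the test. Of 22 macrophage and leukocyte markers 6 were lower and 2 higher, also adjusted over the list alone, and the list was not called (median -0.39, adjusted p = 0.585, median -0.44 with the covariate). Among those with a mean of at least 5 in the higher group, 6 were lower and 0 higher. ITGB2 (-3.15, SE 0.34), SPI1 (-2.51, SE 0.33) and AIF1 (-2.21, SE 0.41) fell. Cardiac muscle markers had 4 of 17 higher and 0 lower, or 2 and 0 adjusted over the list alone (median 0.08, adjusted p = 0.0472, adjusted p = 0.343 with an estimated correlation, median 0.02 with the covariate). Only 1 of these 4, TTN (1.57, SE 0.33), had a mean log2 value of at least 5, and quantile normalization turned the list's median to -0.01 and ended its call (adjusted p = 0.342). The cardiac call was also lost with the covariate (adjusted p = 0.168), with the 3 arrays of widest 3′ to 5′ difference left out (adjusted p = 0.0697), and without any one of static arrays 1, 5 and 6 (adjusted p = 0.0739, 0.0614 and 0.0572) and stretched arrays 5 and 6 (adjusted p = 0.0685 and 0.0543).

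HTR2A, HTR2B and MAOA of the serotonin list rose with stretch. HTR2A, a serotonin receptor, was 6.06 ± 0.55 in stretched and 4.07 ± 0.42 in static tissue (SD, n = 6; change 1.99, SE 0.23, limma adjusted p = 1.2e-06; 1.77 with the covariate). HTR2B, the receptor linked to drug-induced valve disease, was 8.64 ± 1.03 and 6.28 ± 0.60 (change 2.37, SE 0.39, limma adjusted p = 8.9e-05; 1.60 with the covariate), and MAOA, which breaks serotonin down, changed by 2.41 (SE 0.28, adjusted p = 1.9e-06; 2.24 with the covariate). All 3 genes had 6 of 6 stretched arrays above every static array. The serotonin transporter SLC6A4 lay near the bottom of the scale, 2.98 ± 0.25 against 2.76 ± 0.14 (SD, n = 6), and did not pass the test (0.22, SE 0.10, limma adjusted p = 0.0667). It did pass after centring (0.44, adjusted p = 0.00391) and without static array 1, stretched array 2 or stretched array 4 (adjusted p = 0.0335, 0.0450 and 0.0376). With the replicate number as a block it passed as well (limma adjusted p = 0.0499). Of the 11 measured members of the serotonin list 8 were higher and 0 lower, or 9 and 0 adjusted over the list alone (median 0.25, adjusted p = 0.000345, adjusted p = 0.204 with an estimated correlation; with the covariate median 0.10, 3 higher and 0 lower). Only 3 of those 8 had a mean log2 value of at least 5 in the higher group. With dim probe sets left out the list kept 4 members, too few to be tested.

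Heat shock and cell cycle genes were the remaining lists called in this comparison. Of 16 heat shock genes 10 were higher and 0 lower, also adjusted over the list alone (median 0.70, adjusted p = 0.000345, adjusted p = 0.414 with an estimated correlation, median 1.30 with the covariate). DNAJB1 (2.84, SE 0.48), BAG3 (1.5, SE 0.30) and HSPB1 (1.27, SE 0.25) were examples. Another probe set of BAG3 did not pass (0.92, adjusted p = 0.192). Of 23 cell cycle genes 12 were higher and 1 lower, also adjusted over the list alone (median 0.28, adjusted p = 0.000839, adjusted p = 0.0543 with an estimated correlation, median 0.58 with the covariate). Among those with a mean of at least 5, 3 were higher and 1 lower. The mitotic kinase AURKA changed by 2.24 (SE 0.40) and TOP2A by 1.23 (SE 0.26).

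**Figure D2:**
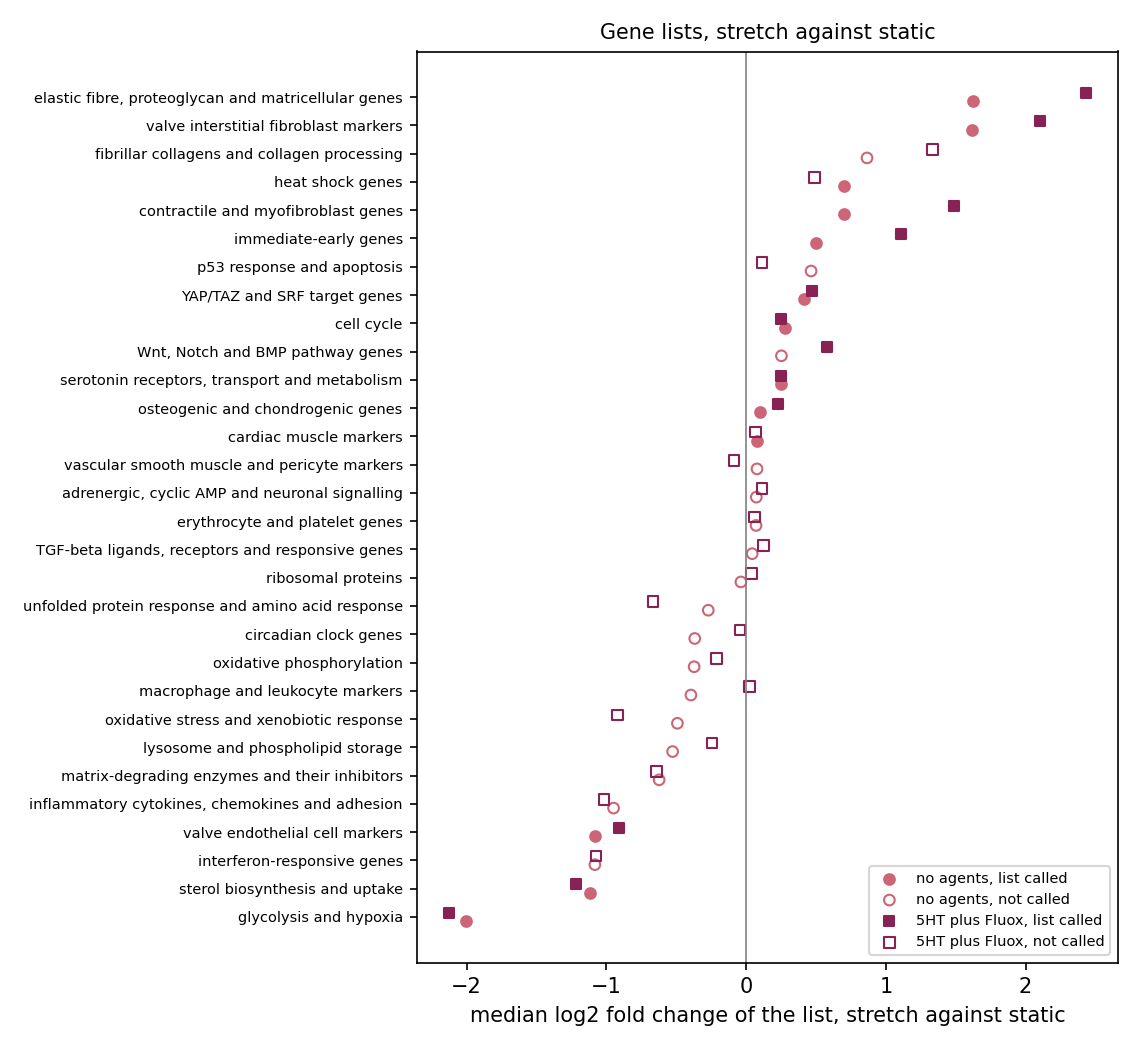
Median log2 change of each of 30 gene lists, stretch against static, without agents (circles) and with 5HT plus Fluox (squares); filled symbols passed the list test at an adjusted p under 0.05 with a preset correlation. Glycolysis and hypoxia genes lie lowest, at -2.00 and -2.12, and elastic fibre, proteoglycan and matricellular genes highest, at 1.62 and 2.43.

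The second comparison asks the same of tissue that received 5HT plus Fluox. The list test again called glycolysis and hypoxia genes (22 of 23 members lower) and endothelial markers (9 of 18 lower, 2 higher) downward. It called elastic fibre and proteoglycan genes (15 of 19 higher), interstitial fibroblast markers (15 of 18) and contractile genes (16 of 20) upward. None of these 5 list calls held with an estimated correlation (adjusted p = 0.136, 0.391, 0.15, 0.156 and 0.156 in that order). The 3′ to 5′ difference was 2.64 against 0.82 log2. Among the rises were those of ISLR (6.84, SE 0.56, adjusted p = 1.6e-08), CILP (6.58, SE 0.66, adjusted p = 2.1e-07) and C1QTNF3 (6.17, SE 0.33, adjusted p = 6.9e-11). MMP1, the interstitial collagenase (-7.77, SE 1.26, adjusted p = 5.5e-05), ECSCR (-7.26, SE 0.38, adjusted p = 4.8e-11) and CDA (-6.83, SE 0.50, adjusted p = 3.8e-09) fell to the bottom of the scale (stretched means 2.57, 2.89 and 2.02), so that their falls were at least that large and have no order of size. Of 23999 probe sets limma called 12527 (52.2%), 6796 higher and 5731 lower; 3631 and 4062 of them were at least 2-fold higher and lower. With the 3′ to 5′ difference as a covariate 3721 were called, 3249 of them among the 12527 and in the same direction. After centring on brighter probe sets 11859 were higher and 4939 lower. Lower calls were again more frequent after quantile normalization (5094 higher, 5286 lower), with dim probe sets left out (3676 and 5311) and with the covariate (1709 and 2012).

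Further rises were those of FXYD7, S100A1, MRAP2, THBS3, COPZ2, PALMD, ALS2CL, the scavenger receptor SCARA5 and TSPAN7, from 5.61 down to 4.81. Falls of similar size were those of the arginine-degrading enzyme ARG1 (-6.69, SE 0.89), SLC16A3 (-6.15, SE 0.10), ACVR1B, IL18BP, SLC2A1 (-5.18, SE 0.42), the acute-phase gene SAA2 (-5.08, SE 0.41), SCD, IL27RA and ZNF697. In all 24 genes 6 of 6 stretched arrays lay beyond every static array. The stretched mean of SLC16A3 (2.58) and the static means of S100A1 (2.25), ALS2CL (2.49), ISLR (2.66), TSPAN7 (2.86) and THBS3 (3.40) also lay near the bottom of the scale, where changes may be compressed. IL18BP lost its call with the covariate (-1.16, adjusted p = 0.726), and another probe set of SAA2 did not pass the test (-0.47, adjusted p = 0.337).

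HTR2A (2.39, SE 0.23, adjusted p = 9.4e-08; 2.07 with the covariate), HTR2B (2.08, SE 0.39, adjusted p = 0.000249) and MAOA (2.87, SE 0.28, adjusted p = 1.7e-07; 2.63 with the covariate) rose in 6 of 6 arrays. The call of HTR2B was lost with the covariate (1.03, adjusted p = 0.190). SLC6A4 did not pass the test (0.13, SE 0.10, adjusted p = 0.291), except after centring (0.33, adjusted p = 0.0224). The serotonin list had 8 of 11 members higher and 0 lower, also adjusted over the list alone (median 0.25, adjusted p = 0.000696, adjusted p = 0.162 with an estimated correlation; with the covariate median 0.11, 2 higher and 0 lower). Of the 8, 4 had a mean of at least 5. ACTA2 was 10.1 ± 0.56 in stretched and 6.31 ± 0.75 in static tissue (SD, n = 6; change 3.80, SE 0.68, limma adjusted p = 0.000163), with 6 of 6 arrays higher.

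Glycolysis and hypoxia genes were lower in 22 of 23 members and higher in 1, also adjusted over the list alone (median -2.12, 4.36-fold lower; adjusted p = 2.7e-11, adjusted p = 0.136 with an estimated correlation, median -1.42 with the covariate). HK1 (-3.30, SE 0.17) and lactate dehydrogenase LDHA (-3.11, SE 0.26) were among them. Sterol genes were lower in 12 of 18 and higher in 0, also adjusted over the list alone (median -1.22, adjusted p = 0.00324, adjusted p = 0.435 with an estimated correlation, median -0.93 with the covariate). Endothelial markers were lower in 9 of 18 and higher in 2, also adjusted over the list alone (median -0.91, adjusted p = 0.0392, adjusted p = 0.391 with an estimated correlation, median -0.72 with the covariate). CDH5 (-4.70, SE 0.35) and ENG (-2.43, SE 0.23) were lower, and AQP1 (3.04, SE 0.39) and LYVE1 (2.32, SE 0.38) were higher. Another probe set of CDH5 did not pass the test (-0.14, limma adjusted p = 0.218). The endothelial call was lost without static array 4 (adjusted p = 0.0695) or stretched array 1 (adjusted p = 0.0510), with dim probe sets left out (adjusted p = 0.119), and without the 3 arrays of widest 3′ to 5′ difference (adjusted p = 0.0525).

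Elastic fibre, proteoglycan and matricellular genes were higher in 15 of 19 members and lower in 0, also adjusted over the list alone (median 2.43, 5.39-fold; adjusted p = 1.3e-09, adjusted p = 0.15 with an estimated correlation, median 2.07 with the covariate). ASPN (4.65, SE 0.46), FBLN1 (4.16, SE 0.38) and BGN (2.74, SE 0.23) were among them. Interstitial fibroblast markers had 15 of 18 higher and 1 lower, or 16 and 1 adjusted over the list alone (median 2.10, adjusted p = 1.0e-07, adjusted p = 0.156 with an estimated correlation, median 2.07 with the covariate). Among them THY1 rose by 4.42 (SE 0.27), and another probe set of THY1 did not pass (0.90, adjusted p = 0.0551). Contractile genes had 16 of 20 higher and 0 lower, also adjusted over the list alone (median 1.49, adjusted p = 7.6e-08, adjusted p = 0.156 with an estimated correlation, median 1.55 with the covariate). TPM1 (3.78, SE 0.43), TAGLN (2.89, SE 0.34) and CNN1 (4.06, SE 0.50) were higher. Osteogenic and chondrogenic genes had 8 of 15 higher and 0 lower, also adjusted over the list alone (median 0.23, adjusted p = 0.00117, adjusted p = 0.15 with an estimated correlation, median 0.97 with the covariate). Fibrillar collagen genes were not called as a list (9 of 16 higher and 4 lower, also adjusted over the list alone; median 1.33, adjusted p = 0.0577, median 0.85 with the covariate). They were called after quantile normalization (adjusted p = 0.0282), with dim probe sets left out (adjusted p = 0.0267) and without static array 6 or stretched array 3 (adjusted p = 0.0497 and 0.0421).

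Immediate-early genes had 10 of 17 higher and 1 lower, or 12 and 1 adjusted over the list alone (median 1.11, adjusted p = 0.000246, adjusted p = 0.162 with an estimated correlation, median 1.59 with the covariate). YAP/TAZ and SRF targets had 7 of 14 higher and 2 lower, also adjusted over the list alone (median 0.47, adjusted p = 0.0196, adjusted p = 0.156 with an estimated correlation, median 0.50 with the covariate). Averaging the probe sets of each gene ended this call (adjusted p = 0.124). Wnt, Notch and BMP pathway genes had 9 of 18 higher and 2 lower, or 10 and 2 adjusted over the list alone (median 0.58, adjusted p = 0.0141, adjusted p = 0.162 with an estimated correlation, median 0.34 with the covariate). Cell cycle genes had 6 of 23 higher and 2 lower, or 5 and 2 adjusted over the list alone (median 0.25, adjusted p = 0.0394, adjusted p = 0.156 with an estimated correlation, median 0.13 with the covariate). The list lost its call after quantile normalization (adjusted p = 0.140), with dim probe sets left out (adjusted p = 0.324) and without static arrays 1 or 2 or stretched array 4 (adjusted p = 0.0541, 0.0610 and 0.0624). AURKA lost its own call with the covariate (1.41, adjusted p = 0.114). Heat shock genes were not called (6 of 16 higher and 1 lower, also adjusted over the list alone; median 0.49, adjusted p = 0.0596). They were called with the covariate (median 1.5, 9 higher and 0 lower, adjusted p = 2.2e-07), without the 3 arrays of widest 3′ to 5′ difference (adjusted p = 0.000920), after quantile normalization (adjusted p = 0.0201), with dim probe sets left out (adjusted p = 0.0131) and without any one of static arrays 4, 5 and 6 or stretched arrays 5 and 6 (adjusted p from 0.0149 to 0.0473).

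**Figure D3:**
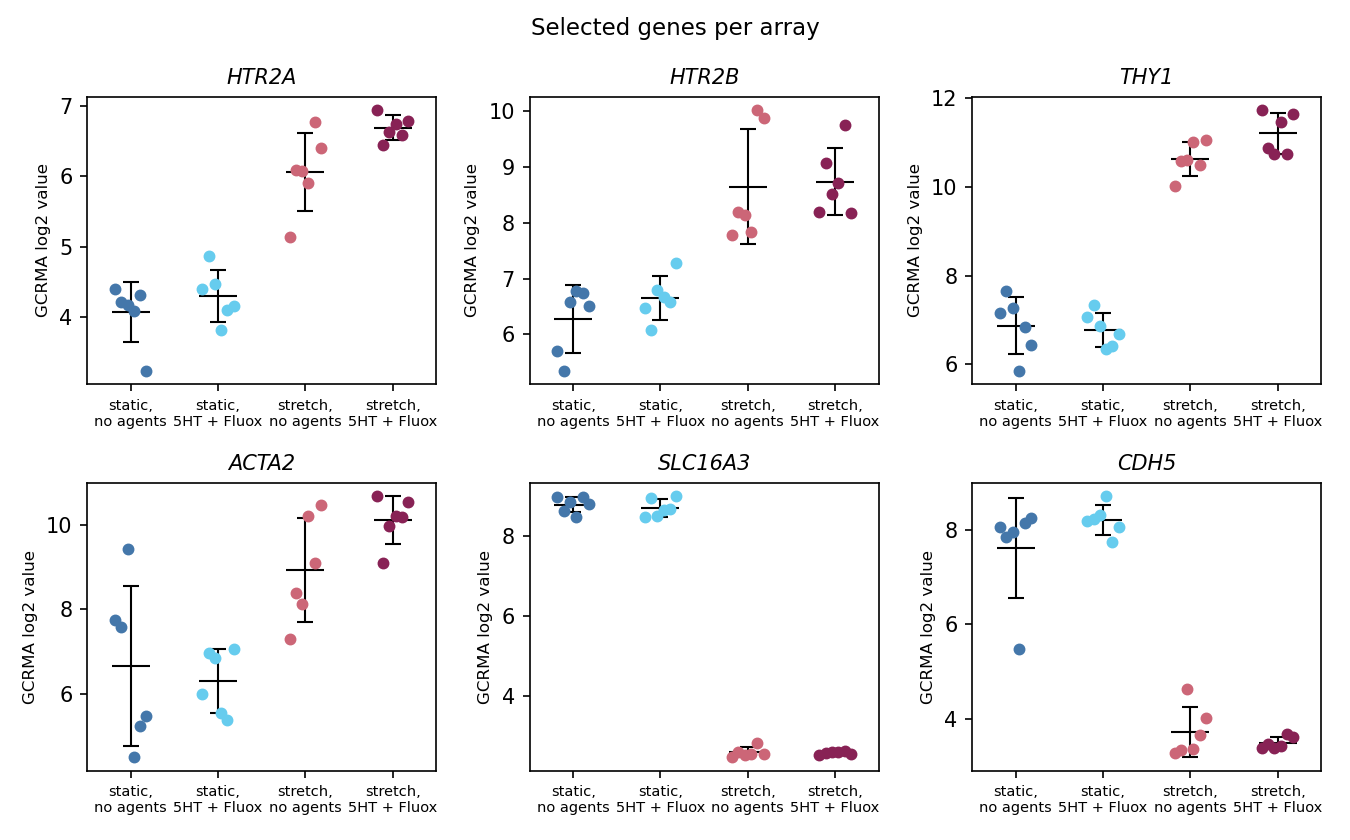
GCRMA log2 values of 6 genes on each of the 24 arrays by group; points are arrays, and the horizontal mark and bars give the group mean and SD (n = 6). HTR2A, HTR2B, THY1 and ACTA2 have higher means in stretched tissue, and SLC16A3 and CDH5 lie near the bottom of the scale there.

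Both stretch effects were compared across genes. Their log2 changes had a Pearson r of 0.898 and a Spearman rho of 0.888 over the 23999 probe sets, which are not independent replicates, and both comparisons use separate arrays. Both also share the wider 3′ to 5′ difference of stretched arrays (by 1.32 and 1.82 log2). A technical shift common to both would add to this agreement and to the shared calls, and was not told apart from stretch. With that difference as a covariate r was 0.879. Calls in both comparisons numbered 4906 higher, where independent lists would share 2001, and 4257 lower, where independent lists would share 1321; 2 probe sets were called in opposite directions. The test of the difference itself, the interaction of stretch and agents, called 0 probe sets with limma (smallest adjusted p = 0.540), and 1791 had an unadjusted p under 0.05. The ordinary linear model without moderation and limma with a trend and robust variances also called 0. The count was 2174 with array weights, 2 without the 3 arrays of widest 3′ to 5′ difference or without treated stretched array 2, and 1 without treated stretched array 5 or untreated stretched array 4 or 5. The smallest unadjusted p among named genes were those of DCAF13 (-1.39, SE 0.30), CA11 (1.26, SE 0.29), CD82 (2.25, SE 0.53) and SLC34A2 (-0.95, SE 0.23), each at an adjusted p of 0.540. HTR2A (0.40, SE 0.32), HTR2B (-0.28, SE 0.55), SLC6A4 (-0.10, SE 0.14) and ACTA2 (1.54, SE 0.96) did not pass either.

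The third comparison asks what 5HT plus Fluox changed in static tissue. CDK16, a cyclin-dependent kinase gene outside the naming rule and so chosen after its values were seen, was the only probe set called by limma (-0.61, SE 0.08, adjusted p = 0.00502), and 422 had an unadjusted p under 0.05. The call was lost in limma with a trend and robust variances, with dim probe sets left out and when only these 2 groups were fitted, where the count was 0. The count was 4 without static array 6 of the untreated group or array 1 of the treated group, 3 without treated array 2 and 2 without untreated array 5. STARD10 (-0.70, SE 0.14, adjusted p = 0.366), PIK3R5 (-0.69, SE 0.15, adjusted p = 0.392), PFKL (-0.95, SE 0.23, adjusted p = 0.868) and PTOV1 (-1.03, SE 0.27) did not pass. The serotonin receptors HTR2A (0.23, SE 0.23) and HTR2B (0.37, SE 0.39), SLC6A4 (-0.01, SE 0.10) and ACTA2 (-0.36, SE 0.68) did not pass.

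In static tissue 6 lists were called, although 0 of their members passed singly, over all genes or adjusted over the list alone. Genes of the unfolded protein and amino acid response shifted upward (median 0.16, 1.12-fold; adjusted p = 6.2e-05, adjusted p = 0.781 with an estimated correlation), as did cell cycle genes (median 0.04, adjusted p = 0.0452, adjusted p = 0.372 with an estimated correlation). Inflammatory cytokines, chemokines and adhesion genes shifted downward (median -0.33, adjusted p = 0.00133, adjusted p = 0.781 with an estimated correlation), with CSF3 at -1.16 (SE 0.36). Macrophage and leukocyte markers (median -0.25, adjusted p = 0.0308, adjusted p = 0.781 with an estimated correlation), lysosome and phospholipid storage genes (median -0.20, adjusted p = 0.0308, adjusted p = 0.798 with an estimated correlation) and interstitial fibroblast markers (median -0.26, adjusted p = 0.0211, adjusted p = 0.798 with an estimated correlation) also shifted downward. The count was 2 without untreated array 1 or 2 or treated array 4 or 5, and 3 without untreated array 3. The upward shift of the unfolded protein response was called when any 1 of the 12 arrays was left out. The inflammatory list was not called without untreated array 3 or 4 or treated array 4 (adjusted p = 0.0578, 0.132 and 0.0559). Neither macrophage nor fibroblast markers were called without untreated array 1, 2 or 3 or treated array 4 or 5 (adjusted p from 0.0506 to 0.194). The lysosome list was not called without untreated array 1 or 2 or treated array 4 or 5 (adjusted p from 0.0506 to 0.591) or with dim probe sets left out (adjusted p = 0.0579). The cell cycle list was not called without untreated array 1, 2 or 3 or treated array 4, 5 or 6 (adjusted p from 0.0780 to 0.181), after quantile normalization (adjusted p = 0.139), with averaged probe sets (adjusted p = 0.0646) or without the 3 arrays of widest 3′ to 5′ difference (adjusted p = 0.0621). The 3′ to 5′ difference was 0.77 and 0.82 log2 in these groups. With it as a covariate the medians were 0.18 for the unfolded protein response, 0.04 for the cell cycle, -0.29 for inflammatory genes, -0.24 for macrophage markers, -0.18 for the lysosome list and -0.26 for fibroblast markers.

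The fourth comparison asks what the agents changed in stretched tissue. limma called 14 probe sets, 11 higher and 3 lower, and 3555 had an unadjusted p under 0.05. The 3 with a gene symbol were DCAF13 (-1.45, SE 0.21, adjusted p = 0.0198, lower in 6 of 6 arrays), CA11, a carbonic anhydrase-related gene (1.28, SE 0.20, adjusted p = 0.0198), and NIP7, a ribosome biogenesis factor (-0.46, SE 0.08, adjusted p = 0.0439). CA11 and NIP7 fall outside the naming rule and were chosen after their values were seen. This count moved widely with single arrays. It was 1647 without untreated array 6, 822 without untreated array 5, 191 without untreated array 4 and 162 without treated array 2. It was 0 without untreated array 2 or treated array 6, 1 without untreated array 3, 2 without treated array 1, 3 without treated array 5, 5 without untreated array 1 or treated array 3, and 6 without treated array 4. With array weights it was 3733, without the 3 arrays of widest 3′ to 5′ difference 321, and with that difference as a covariate 5. It was 0 when only these 2 groups were fitted. With the replicate number as a block it was 1, DCAF13 (limma adjusted p = 0.0490), while CA11 (0.0520) and NIP7 (0.0539) lost their calls. HTR2A (0.63, SE 0.23, adjusted p = 0.197), HTR2B (0.09, SE 0.39, adjusted p = 0.968), SLC6A4 (-0.11, SE 0.10, adjusted p = 0.701) and ACTA2 (1.18, SE 0.68, adjusted p = 0.454) did not pass.

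In stretched tissue 7 lists were called, again with 0 members passing over all genes. Elastic fibre, proteoglycan and matricellular genes shifted upward (median 0.42, 1.33-fold; adjusted p = 0.000701, adjusted p = 0.679 with an estimated correlation), with 0 members passing adjusted over the list alone. Contractile genes (median 0.48, adjusted p = 0.00248, adjusted p = 0.707 with an estimated correlation; 0 adjusted over the list alone), fibrillar collagen genes (median 0.50, adjusted p = 0.00746, adjusted p = 0.455 with an estimated correlation; 1 adjusted over the list alone) and interstitial fibroblast markers (median 0.50, adjusted p = 0.00746, adjusted p = 0.737 with an estimated correlation; 0 adjusted over the list alone) shifted the same way. COL5A1 (0.74, SE 0.18, adjusted p = 0.0871) and LOXL1 (1.39, SE 0.48, adjusted p = 0.175) are examples of members that did not pass. The mean of the contractile list was 0.31, and DES, its member with the smallest p, read -2.99 (SE 0.90, adjusted p = 0.131). Circadian clock genes had a median of 0.69 (adjusted p = 0.00329, adjusted p = 0.455 with an estimated correlation), 4 of 7 being higher adjusted over the list alone, and immediate-early genes a median of 0.25 (adjusted p = 0.0162, adjusted p = 0.737 with an estimated correlation), 2 of 17 being higher adjusted over the list alone. NFIL3 (0.63, SE 0.14, adjusted p = 0.0763), PER1 (0.86, SE 0.24, adjusted p = 0.121) and KLF2 (1.05, SE 0.26, adjusted p = 0.0909) did not pass over all genes. Oxidative stress and xenobiotic genes shifted downward (median -0.35, adjusted p = 0.0418, adjusted p = 0.737 with an estimated correlation; 0 adjusted over the list alone). This call was lost with the covariate (adjusted p = 0.267), with averaged probe sets (adjusted p = 0.183), with dim probe sets left out (adjusted p = 0.0641), without the 3 arrays of widest 3′ to 5′ difference (adjusted p = 0.0511) and without any one of untreated arrays 1, 2, 3 and 4 or treated arrays 5 and 6 (adjusted p from 0.0628 to 0.197). With the covariate the medians were 0.46 for elastic fibre and proteoglycan genes, 0.51 for contractile genes, 0.30 for fibrillar collagens, 0.40 for fibroblast markers, 0.71 for clock genes, 0.35 for immediate-early genes and -0.09 for oxidative stress genes. The count of lists was 11 without treated array 1. The fibroblast markers were not called without untreated array 1 (adjusted p = 0.0794). The immediate-early genes were not called without untreated array 1 or 6 or treated array 3 or 4 (adjusted p from 0.0628 to 0.112) or with dim probe sets left out (adjusted p = 0.0641).

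The effects of the agents in static and in stretched tissue, which come from separate arrays, had a Pearson r of 0.107 and a Spearman rho of 0.109 across the 23999 probe sets. Probe sets called in both numbered 0, against 1 and 14 called in either. The correlation was -0.034 without untreated stretched array 1 and -0.041 with the 3′ to 5′ difference as a covariate.

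The authors' deposited table of an analysis of variance gives Benjamini-Hochberg adjusted p-values for the 4 pairwise comparisons over 24123 probe sets, controls included. At an adjusted p under 0.05 the authors' deposited table calls 13926 for stretch without agents, 13626 for stretch with agents, 1 for the agents in static tissue and 7 for the agents in stretched tissue. An ordinary linear model of the deposited values put 100% of the probe sets on the same side of that threshold as the authors' deposited table in each comparison, and limma's moderated test put 94.2%, 94.7%, 100% and almost all (99.96%) there. For HTR2B the authors' deposited table gives fold changes of 5.15 without agents and 4.24 with agents.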

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

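The tests of RNA integrity as a whole cause, of the narrower spread of values and of endothelial cell number were chosen after the result was seen. Those of integrity as part of the cause and of signal level were written before.

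Most probe sets (12600 of 23999) differed between stretched and static tissue without agents, while the 3′ to 5′ difference rose by 1.32 log2 on the same arrays. With that difference as a covariate 5176 probe sets were called (2789 to 7261 without any single array), where other splits of the arrays gave at most 1612. This cannot decide on integrity as the whole cause. The difference did not overlap between static arrays (0.57 to 0.97 log2) and stretched arrays (0.98 to 4.66), so the fit extrapolates. In addition, 2 control genes may track integrity incompletely. A narrower spread of log2 values in stretched arrays as the whole cause is argued against by 9813 calls after quantile normalization (at least 8315 without any single array). Integrity as part of the cause stays open: its slope within stretched arrays with agents correlated with the stretch effect without agents at r = 0.142 across probe sets (exact permutation test over the 6 arrays, p = 0.319), which lies under the bound of 0.2 set in advance against it, but by less than the SD of 0.242 over permutations, a margin that was applied after the value was seen. Stretched arrays with agents held 1 array with a far wider difference (4.66, the others 1.85 to 2.98). The same test within untreated stretched arrays was not run. There, looked at afterwards, array 1 had a difference of 0.98 and a score of -0.10 on the first principal component, below 0 like all static arrays. Arrays 2 to 4 had 1.63 to 2.42 and 0.11, and arrays 5 and 6 had 2.31 and 3.06 and scores of 0.32 and 0.31. Stretch itself, and the sutures and bioreactor that only stretched tissue met, also stay open and were not tested apart. Separate handling of stretched and static samples or arrays stays open too, since no batches or dates were given and the spiked hybridisation control BioB also read higher on stretched arrays (1.95 with agents, adjusted p = 0.00618; 1.45 without, adjusted p = 0.0577).

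Endothelial markers were lower in stretched tissue without agents (median -1.08). With the 3′ to 5′ difference as a covariate the median was -0.92 (-1.16 to -0.79 without any single array). That difference did not overlap between static and stretched arrays and rests on 2 control genes. Integrity as the whole cause therefore stays undecided. Fewer endothelial cells as the whole cause would lower all markers made only by these cells. Of the 9 members with a static mean of at least 5, 8 were lower and AQP1 was higher (2.35). Their changes had an SD of 2.49 around a mean SE of 0.39. That spread cannot decide, since falls to near the bottom of the scale, as of ECSCR and CDH5, are limited by the starting level. The rise of AQP1 cannot decide either, since its expression in other cells was not examined. Fewer endothelial cells, alone or together with changes within cells, may remain as a cause, as does stretch itself. These were not tested apart.

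Glycolysis and hypoxia genes were lower in stretched tissue without agents (median -2.00). With the covariate the median was -1.64 (-1.82 to -1.39 without any single array). The covariate did not overlap between static and stretched arrays and rests on 2 control genes, so integrity as the whole cause stays undecided here too. The high signal of these genes is argued against by 10000 random lists matched on mean expression: the median lay at percentile 0, the lowest random list having -1.07. Oxygen and nutrient supply may differ between the bioreactor and static culture, and this and stretch itself remain open and untested.

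Control probe sets, which enter no comparison of genes, differed between stretched and static arrays. The mean 3′ to 5′ difference was higher by 1.32 without agents and 1.82 with agents, 18S by 1.90 and 1.35, 28S by 2.07 and 2.69, and the hybridisation control BioB by 1.95 with agents (exact permutation tests, each adjusted p at or under 0.0115).

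The interaction of stretch and agents was called for 7 lists with camera, with 0 single probe sets called by limma (1791 at an unadjusted p under 0.05). Of 100 splits of the arrays, the real one included, 51 gave as many lists, so chance cannot be excluded for this count. Values are the log2 change with agents minus that without, as medians. Above 0 were those of fibrillar collagens (0.66, adjusted p = 0.00131, adjusted p = 0.443 with an estimated correlation), elastic fibre and proteoglycan genes (0.74, adjusted p = 9.4e-05, adjusted p = 0.449 with an estimated correlation), contractile genes (0.63, adjusted p = 0.000549, adjusted p = 0.449 with an estimated correlation), interstitial fibroblast markers (0.65, adjusted p = 0.000499, adjusted p = 0.449 with an estimated correlation) and circadian clock genes (0.62, adjusted p = 0.00820, adjusted p = 0.449 with an estimated correlation). Below 0 were those of the unfolded protein response (-0.43, adjusted p = 0.000549, adjusted p = 0.747 with an estimated correlation) and of heat shock genes (-0.43, adjusted p = 0.0103, adjusted p = 0.905 with an estimated correlation). Adjusted over the list alone, 3 collagen and 3 elastic fibre genes passed, and 0 of the other 5 lists. With the covariate the medians of these 7 lists were 0.52, 0.63, 0.65, 0.64, 0.66, -0.26 and -0.16 in the same order. A value above 0 need not be a larger effect: the median stretch change of clock genes was -0.37 without and -0.04 with agents, and that of the unfolded protein response -0.27 and -0.66. Immediate-early genes, not called here, were called with the covariate (adjusted p = 0.00380), without the 3 arrays of widest difference (adjusted p = 0.00186) and in 11 of the 24 fits without 1 array. The heat shock call was lost with the covariate (adjusted p = 0.274) and without treated stretched array 5 or 6 or untreated stretched array 4 (adjusted p = 0.136, 0.0803 and 0.0648).

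Single arrays lay far from the other 5 of their group in 30 of 548 groups examined, by Dixon's criterion. Chance gives about 1 in 20 such groups. Values are log2. In stretched array 6 without agents HSPA6 (10.53), HBEGF (3.53), DNAJB1 (11.64), HSPB1 (11.33) and GADD45A (11.54) lay below the others. In stretched array 5 with agents the GAPDH 3′ to 5′ difference (4.27, others 1.16 to 2.29), ACVR1B (6.23), SLC6A4 (3.09) and CSF3 (3.21) lay above and ENO2 (7.57) below. In static array 4 without agents ECSCR (7.36), CDH5 (5.47) and TAGLN (8.43) lay below. DES (3.12) and SLC6A4 (3.03) were high in static array 1 without agents, and in static array 6 without agents HTR2A (3.24) was low and HBB (8.94) high. SLC16A3 (2.83) was high in stretched array 5 without agents, and in stretched array 1 without agents CDA (5.99) was high and AQP1 (10.50) low. With agents, ARAP3 (3.27) was high in stretched array 1, MAOA (10.21) low in stretched array 2, and in stretched array 6 ITGB2 (4.51) was high and PIK3R5 (1.64) low. FBLN1 (8.24), PFKL (5.82) and MGST1 (11.12) were high in static array 2 with agents, AQP1 (11.03) and PTOV1 (3.03) in static array 4, and GP9 (1.45) was low in static array 3.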

How the results depend on the processing

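Of the alternatives in this part, the 3′ to 5′ difference as a covariate and leaving out the 3 arrays in which it was widest were chosen after the data were seen. The match with the authors' deposited table without moderation was not planned either. The others were planned.

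Counts for both stretch comparisons stayed within 1.5 times of 12600 and 12527 except as follows. Without dim probe sets 8121 were called without agents, from fewer probe sets tested, and the covariate gave 5176 and 3721. Without any single array the ranges were 10141 to 14722 and 10949 to 12780. Without dim probe sets the serotonin (4 members), cardiac and erythrocyte lists (2 each) were too small to test. Lists called were 12 to 14 and 11 to 14 without any single array, and 0 in all 5 contrasts with an estimated correlation.

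For the agents in static tissue, trend and robust variances, leaving out dim probe sets, and fitting only the 2 groups each gave 0 calls; single arrays left out gave 1 to 4 probe sets and 2 to 9 lists. In stretched tissue the 14 calls became 1 with the replicate number as a block, 9 with trend and robust variances, 7 without moderation, 3 without dim probe sets, 31 after quantile normalization, 0 with only the 2 groups, 3733 with array weights, 5 with the covariate and 321 without the 3 arrays; single arrays left out gave 0 to 1647 probe sets and 5 to 11 lists. The lowest array weights were 0.137 and 0.149, in stretched arrays 5 and 6 without agents. The interaction gave 2174 calls with array weights, 2 without the 3 arrays, and 0 to 2 probe sets and 7 or 8 lists with single arrays left out. The cause of these changes was not tested. Some lists not called for the agents were called in other fits. In static tissue heat shock genes were called upward (adjusted p = 0.0315 with the covariate, 0.0339 after quantile normalization, 0.0317 without dim probe sets, 0.0156 with averaged probe sets, 0.0490 without the 3 arrays), adrenergic and neuronal genes upward and elastic fibre and proteoglycan genes downward (each 0.0481 with the covariate). Without single arrays these 3 were called in 4, 3 and 4 of 12 fits, and interferon-responsive and contractile genes in 3 and 1, downward. In stretched tissue heat shock (0.0473 after quantile normalization) and interferon-responsive genes (0.0299 with averaged probe sets) were called downward, and without single arrays in 5 and 5 of 12 fits, as were inflammatory genes in 3 and the unfolded protein response in 4.

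The correlation of both stretch effects ranged from 0.853 to 0.920 without any single array. That of the agent effects ranged from -0.034 (without stretched array 1 without agents) to 0.19 and was -0.041 with the covariate; the cause was not tested. Calls matched the authors' deposited table on 97.2% of probe sets on average over 4 comparisons, and on 100% without moderation.

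The replicate numbers were not used as pairs in the main fit. Arrays of the same number in both groups of a comparison, after removing group means, did not all correlate above 0.1 in any comparison. This does not rule out that some of them share an animal or handling, above all in static tissue, where most pairs passed. The correlation passed 0.1 in 3 of 6 cases for stretch without agents (-0.22 to 0.40), 1 with agents (-0.26 to 0.22), 5 for the agents in static tissue (-0.11 to 0.59) and 4 in stretched tissue (-0.05 to 0.42), and the own number matched best in 1, 0, 3 and 1. A pairing within static or within stretched tissue alone was not fitted. As a block, with 1 effect per number over all 4 groups, the replicate numbers gave 12899, 12946, 1, 1 and 0 calls. The 1 in stretched tissue was DCAF13 (limma adjusted p = 0.0490, with CA11 at 0.0520 and NIP7 at 0.0539). Under the block the cardiac list without agents (adjusted p = 0.0551), the endothelial list with agents (adjusted p = 0.0550) and the cell cycle list for the agents in static tissue (adjusted p = 0.0556) were not called, and SLC6A4 without agents was (0.22, adjusted p = 0.0499). Called there in addition were, for the agents in static tissue, adrenergic and neuronal genes upward and interferon-responsive genes downward (each adjusted p = 0.0495), and in stretched tissue interferon-responsive genes downward (adjusted p = 0.0150).

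Other probe sets of the same symbol had the opposite sign, the cause not tested. Without agents these were DES (-0.46), PMEPA1 (-2.06 and -0.67), GUSB (0.086), GSR (0.63 and 1.16), TEK (0.048 and 0.17), PDGFRB (0.0041), CREM (-0.017) and BHLHE40 (0.11). With agents they were PMEPA1 (-0.98 and -0.54), GSR (0.95 and 1.27), DKK2 (2.49), TEK (0.085), PDGFRB (0.033), CREM (-0.32 and -0.55), BHLHE40 (0.088) and RPL35 (-0.023). With the covariate HBB (0.0059), GP9 (-0.027) and ARNTL (1.17) turned sign with agents. Near the bottom of the log2 scale, at about 2 to 3 as for SLC6A4, differences between groups are compressed.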

Other observations

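All list tests and splits in this part were planned. The comparison of the first principal component with BioB and the values with the 3′ to 5′ difference as a covariate were chosen after the result was seen. That difference was 1.32 and 1.82 log2 wider in stretched than in static tissue, without and with agents.

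Called genes of matrix turnover and inflammation went both ways with stretch, more of them downward in the main fit. Among members with a mean of at least 5 in the higher group, matrix-degrading enzymes and inhibitors had 2 higher and 9 lower without agents. With agents they had 4 and 10. Inflammatory genes of that level had 1 higher and 12 lower without agents and 1 and 9 with agents. Of 19 matrix-degrading enzymes and inhibitors 5 were higher and 9 lower without agents, or 5 and 10 adjusted over the list alone (median -0.62, -0.64 with the covariate, adjusted p = 0.585). With agents 6 were higher and 10 lower, also adjusted over the list alone (median -0.64, -0.39 with the covariate, adjusted p = 0.493). The inhibitor TIMP3 rose by 3.73 (SE 0.34) and 4.76 (SE 0.34), and the membrane-bound collagenase MMP14 changed by -3.14 (SE 0.30) and -2.51 (SE 0.30). Of 30 inflammatory genes 2 were higher and 12 lower without agents, or 2 and 11 adjusted over the list alone (median -0.95, adjusted p = 0.182). With agents 2 were higher and 11 lower, or 2 and 10 adjusted over the list alone (median -1.02, adjusted p = 0.193). With the covariate these medians were -0.25 (5 higher and 5 lower) and -0.02 (4 and 3), and the test pointed upward in both. The granulocyte growth factor CSF3 changed by -2.96 (SE 0.36) and -2.11 (SE 0.36), and the prostaglandin synthase PTGES by -2.90 (SE 0.46) and -3.43 (SE 0.46). Interferon-responsive genes had 1 of 15 higher and 5 lower without agents, also adjusted over the list alone (median -1.08, adjusted p = 0.585). With agents 1 was higher and 6 lower, or 1 and 5 adjusted over the list alone (median -1.07, adjusted p = 0.327). With the covariate the interferon medians were 0.25 and -0.03. Of 11 TGF-beta genes 4 were higher and 1 lower without agents, also adjusted over the list alone (median 0.04, 0.51 with the covariate, adjusted p = 0.418). With agents 4 were higher and 1 lower, or 5 and 2 adjusted over the list alone (median 0.13, adjusted p = 0.327; 1.28 and 0.0211 with the covariate).

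Organelle and stress genes were mixed as well. Oxidative phosphorylation genes had 2 of 31 higher and 10 lower without agents, or 1 and 10 adjusted over the list alone (median -0.37, -0.26 with the covariate, adjusted p = 0.322). With agents 5 were higher and 10 lower, also adjusted over the list alone (median -0.21, -0.02 with the covariate, adjusted p = 0.493), SDHA changing by -1.65 (SE 0.35) and -1.91 (SE 0.35). Lysosome and phospholipid storage genes had 2 of 22 higher and 5 lower, or 2 and 3 adjusted over the list alone (median -0.53, -0.32 with the covariate, adjusted p = 0.585). With agents 3 were higher and 4 lower, also adjusted over the list alone (median -0.24, -0.09 with the covariate, mean -0.14, with the test pointing upward; adjusted p = 0.820). The unfolded protein and amino acid response had 5 of 20 higher and 7 lower, also adjusted over the list alone (median -0.27, with the test pointing upward; adjusted p = 0.926). With agents 0 were higher and 10 lower, or 3 and 11 adjusted over the list alone (median -0.66, adjusted p = 0.172). With the covariate both medians turned sign, to 0.30 (7 higher and 2 lower) and 0.03 (4 and 4). The chaperone PDIA4 changed by -1.0 (SE 0.14) and -1.31 (SE 0.14). Oxidative stress genes had 2 of 24 higher and 6 lower, also adjusted over the list alone (median -0.49, adjusted p = 0.418). With agents 2 were higher and 11 lower, also adjusted over the list alone (median -0.92, adjusted p = 0.145), MGST1 changing by -2.78 (SE 0.34) and -2.99 (SE 0.34). With the covariate the medians were 0.20 and -0.02, with 1 higher and 2 lower in both. Genes of p53 response and apoptosis had 5 of 17 higher and 3 lower, also adjusted over the list alone (median 0.47, adjusted p = 0.210; 0.43 and 0.0366 with the covariate). With agents 5 were higher and 6 lower, also adjusted over the list alone (median 0.11, -0.05 with the covariate, mean -0.10, adjusted p = 0.642). GADD45A rose by 3.15 (SE 0.31) and 3.11 (SE 0.31), and BAX changed by -2.57 (SE 0.35) and -2.18 (SE 0.35). Wnt, Notch and BMP genes had 6 of 18 higher and 3 lower without agents, also adjusted over the list alone (median 0.25, also with the covariate, adjusted p = 0.0653; called after quantile normalization, with averaged probe sets and without static array 3 or 4 or stretched array 1 or 3, adjusted p from 0.0267 to 0.0480), LEF1 rising by 1.97 (SE 0.31).

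The remaining markers and lists were not called as lists in the comparisons given here. Macrophage and leukocyte markers with agents had 2 of 22 higher and 6 lower, also adjusted over the list alone (median 0.03, mean -0.37, median -0.15 after quantile normalization and 0.01 with the covariate, camera adjusted p = 0.976). Those with a mean of at least 5 in the higher group had 0 higher and 6 lower. Cardiac muscle markers with agents had 2 of 17 higher and 0 lower, 0 adjusted over the list alone (median 0.07, -0.02 after quantile normalization and 0.02 with the covariate; adjusted p = 0.165). Vascular smooth muscle and pericyte markers had 3 of 11 higher and 1 lower in both comparisons, also adjusted over the list alone without agents but 2 and 0 with agents (medians 0.08 and -0.09, the latter 0.11 after centring and with a mean of 0.51; adjusted p = 0.210 and 0.327; with the covariate medians 0.48 and 0.33, adjusted p = 0.0441 and 0.0334). Erythrocyte and platelet genes had 2 of 8 higher and 1 lower without agents, also adjusted over the list alone, and 1 and 3 with agents, or 0 and 1 adjusted over the list alone (medians 0.07 and 0.06, means -0.22 and -0.22, medians -0.02 and -0.02 after quantile normalization, -0.02 and 0.01 with the covariate; adjusted p = 0.596 and 0.688). Adrenergic, cyclic AMP and neuronal genes had 5 of 12 higher and 2 lower without agents and 3 and 2 with agents, also adjusted over the list alone (medians 0.07 and 0.11, means -0.14 and -0.23, medians 0.10 and 0.11 with the covariate; adjusted p = 0.241 and 0.351). Circadian clock genes had 1 of 7 higher and 4 lower without agents and 2 and 1 with agents, also adjusted over the list alone (medians -0.37 and -0.04, the latter 0.13 after quantile normalization and 0.16 after centring, with the covariate -0.50 and 0.03, camera adjusted p = 0.574 and 0.528), BHLHE40 changing by -3.33 (SE 0.56) and -2.30 (SE 0.56). The call of BHLHE40 with agents was lost with the covariate (-0.08, limma adjusted p = 0.952). Ribosomal protein genes had 5 of 28 higher and 8 lower without agents, or 4 and 8 adjusted over the list alone, and 7 and 8 with agents, also adjusted over the list alone (medians -0.04, which was 0.18 after centring, and 0.04, with the covariate -0.02 and 0.06; adjusted p = 0.940 and 0.642).

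Of 315 symbols with at least 2 called probe sets of a mean of at least 5 for stretch without agents, 48 (15.2%) had them in both directions. The first principal component held 60.2% of the variance of the 24 arrays and the second 10.1%. In each of the 4 groups the array with the highest BioB reading also had the highest score on the first. Stretched array 1 without agents read lowest of its group for BioB (8.24) and scored -0.10, below 0 like all static arrays. Stretched array 5 without agents read 11.62 and scored 0.32. BioB is spiked in, so a technical part of this component is possible and was not tested.

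Each result was set against 100 of the 462 splits of the same 12 arrays, the real one included, or as many splits for results of all arrays. The splits were not balanced for the real groups, so many of them keep part of the real difference. A high count or correlation in another split of static and stretched arrays may therefore come from the stretch effect. Chance is argued against for both stretch counts, which 1 of the 100 splits drawn reached in each case, the real one. The counts were 12600 against at most 11087 in other splits, and 12527 against 4197. Animals that arrays may share were not taken into account in the splits. The first margin is narrower than the effect of single arrays, the count being 10141 without stretched array 5. The correlation of both stretch effects was also reached by 1 of 100 splits, the real one. Its 0.898 passed the highest other, 0.896, by less than its jackknife SE of 0.071, so this test cannot decide on chance. Chance cannot be excluded for the agents in static tissue (19 of 100, 1 call against up to 537), the agents in stretched tissue (21 of 100, 14 against 3527) and the interaction (100 of 100, 0 against 8). Splits calling several times the real counts may point to a structure of the samples, and what it is was not tested. For the list counts of stretch chance was not excluded, but splits that keep part of the stretch effect cannot decide this. Of 100 splits 7 gave as many as the 13 lists without agents (highest other 16) and 28 as many as 12 with agents (17). For the other list counts chance cannot be excluded. As many as 6 lists for the agents in static tissue came from 79 splits (highest other 15). As many as 7 came from 35 for the agents in stretched tissue (15) and from 51 for the interaction (12). The correlation of the agent effects, 0.107, was reached in size by 65 of 100 splits (highest other 0.410).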
